A study of Sus scrofa with 8 samples.

How the data were processed

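Olfactory epithelium of newborn pigs was profiled by mRNA sequencing in 8 libraries. Of these, 4 came from wild-type piglets (numbered 5, 9, 12 and 23) and 4 from piglets without a functional CFTR gene (numbered 6, 18, 20 and 21). CFTR encodes the chloride and bicarbonate channel that is defective in cystic fibrosis. Per the labels, the tissue was dissected and frozen, RNA was purified on columns with DNase treatment, and the libraries were made with an Illumina TruSeq kit. The authors deposited raw read counts per gene, with no normalization, in a table whose layout per the file headers is that of featureCounts output. FastQC, STAR 2.4.0, featureCounts, Subread 1.5.0-p3, HTSeq and DESeq2 are named in the submitters' processing notes, with no role or order. The genome build is not given in the sources used here, and neither is whether reads were counted by strand, so overlapping and antisense genes are uncertain. Each library is labelled as a separate piglet, so p-values measure the spread between animals. No litter, sex or sequencing batch is given in the labels.

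The table held 25880 pig genes, which took at least 99.9982% of the reads of every library and alone entered the library sizes and tests. Identifiers of spike-in and control sequences (92 ERCC, 7 SIRV and 1 phiX) had 0 reads. A further 5888 identifiers on an extra sequence of unstated origin took 94 to 727 reads per library and were left out. Gene symbols were paired with 14857 identifiers through a table of gene names. Another 1322 identifiers were named by position, where at least 50% of both gene spans overlapped in the RefSeq table of assembly Sscrofa11.1, and 9701 had no symbol. Naming by position was checked on genes with a known symbol. Of 13497 genes paired by symbol, 99.8% overlapped in position, and of 12528 known genes with a position match, 94.7% received their own symbol. Values named by position are marked where they are printed. Several markers, among them OMP, KRT5, KRT14, CYP2G1 and PCNA, were not matched to an identifier and were not analysed here.

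Library totals ranged from 30836904 to 43253395 counts. Counts were fitted with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, edgeR's default filter on low counts and genotype as the factor, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The filter kept 17175 genes, and the biological coefficient of variation was 26.5%. Standard errors were derived from the F statistic, and CPM values were scaled by TMM. The pipeline was tested on simulated data with the means and library sizes of this comparison and 17175 genes. Of 50 genes changed at each size, edgeR called 22% at 1.5-fold, 52% at 2-fold, 90% at 4-fold and 96% at 8-fold, and 8.45% of its calls were unchanged genes. For DESeq2 1.42.0 these shares were 42%, 66%, 94% and 98%, and 25% of its calls were unchanged genes. For limma 3.58.1 with voom, 7.86% of the calls were unchanged genes. The changed genes were drawn from those with a mean of at least 1 CPM, so the shares called do not cover rarer transcripts. Genes were simulated independently of each other, so the shares of unchanged genes do not measure the error rate where genes vary together.

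Marker and response lists (28) for cells of the olfactory mucosa, cells that a dissection could bring along and processes relevant to cystic fibrosis were tested with camera on voom values at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. A simulated shift of -0.5 in log2 of the unfolded protein response list was recovered with an adjusted p of 4.8e-29, and 1 other list was called. Genes were drawn independently in this simulation, whereas the estimated correlation of that list in the data was 0.233. The simulation therefore does not show how the preset correlation performs on these data. Camera with an estimated correlation, fry and an exact permutation test of each list's mean log2 CPM were run beside it. With 4 libraries against 4, the smallest two-sided p an exact permutation can give is 0.0286. List medians are over edgeR log2 fold changes unless named as voom medians, which the alternatives use. Counts of list members are given over all genes and adjusted over the list alone.

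The groups, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took CFTR, the 12 genes in each direction with the largest changes among called genes with a symbol, a mean of at least 1 CPM and no overlap between the groups, or, where fewer than 5 passed, the 5 with the smallest p, and in each list up to 4 members with the smallest p. Genes named outside it are marked as chosen after their values were seen. The alternatives comprised other normalizations, filters and thresholds, DESeq2, limma with sample quality weights, a surrogate variable from sva 3.50.0, and the omission of each library in turn. Alternatives for sex, for stromal content and for libraries that stood apart were added after the data were seen. Library pairs within a group differed by 31.8 to 257 times the sampling variance of their counts, so no library was a copy of another in its group. Pairs across the groups were not checked in this way. Figures were drawn with matplotlib 3.10.9.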

Results

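The data comprised RNA-seq counts from the olfactory epithelium of 8 newborn piglets, 4 wild-type and 4 CFTR-knockout, collected to examine the molecular pathology behind the loss of smell in cystic fibrosis. Wild-type libraries held 30836904 to 42281883 counts and knockout libraries 39915150 to 43253395. Between 19931 and 20407 genes were detected per library. Correlations of log2 expression across genes, which are not independent replicates, were 0.965 to 0.983 within the wild-type group, 0.961 to 0.984 within the knockout group and 0.960 to 0.981 between the groups.

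CFTR, the disrupted gene, was lower in every knockout library than in every wild-type library. Its expression (ENSSSCG00000016626, chromosome 18, 28627719 to 28819815 on the minus strand, build not stated) was 40.4 ± 10.9 CPM in wild-type piglets and 6.84 ± 1.36 CPM in knockout piglets (SD, n = 4 each). Read counts were 2352, 1083, 1407 and 1573 in wild-type piglets 5, 9, 12 and 23, and 277, 188, 326 and 354 in knockout piglets 6, 18, 20 and 21. The transcript was thus still counted in the knockout, at 16.9% of the wild-type level. The log2 fold change was -2.56 ± 0.21 (SE), a 5.90-fold lower level with an edgeR Benjamini-Hochberg adjusted p of 0.0115. The adjusted p was above 0.05 without wild-type piglet 23 (0.0541), without knockout piglet 6 (0.120), without knockout piglet 20 (0.0510) and in the 6 libraries with no read of the Y-linked genes EIF1AY and KDM5D (0.0607), with a log2 fold change between -2.77 and -2.52 in these fits.

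**Figure D1:**
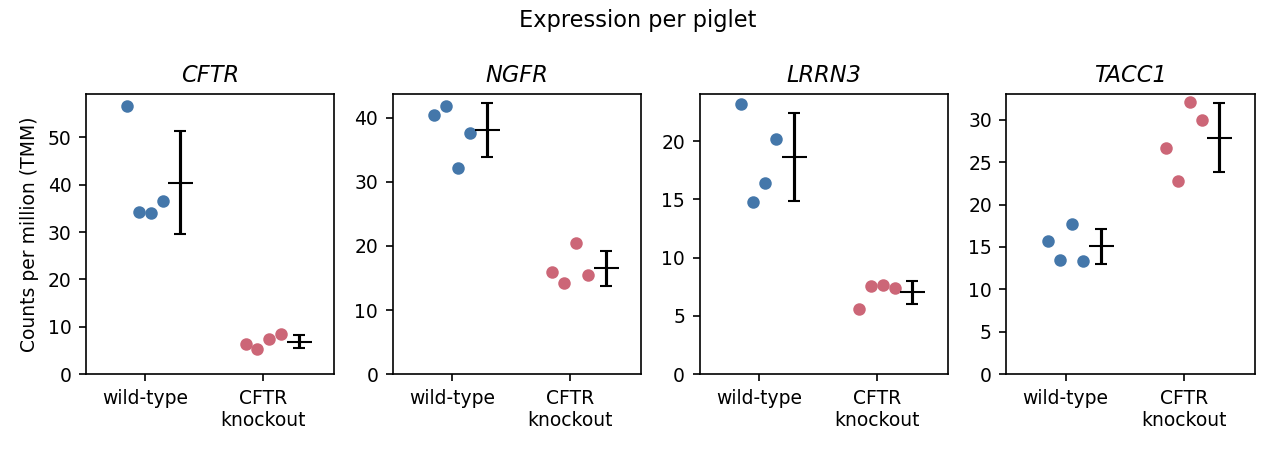
Expression of CFTR, NGFR, LRRN3 and TACC1 in TMM-scaled CPM (vertical axes, from 0) in 4 wild-type (blue) and 4 CFTR-knockout (red) piglets, with piglets as points and the mean and SD in black. CFTR lay between 5.24 and 8.37 CPM in the knockout piglets and between 34.0 and 56.6 CPM in the wild-type piglets.

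The comparison of the transcriptomes asked which other genes differ without CFTR. Among genes with a symbol and a mean of at least 1 CPM, those with the smallest p on the lower side after CFTR were NGFR, the low-affinity neurotrophin receptor of glia and progenitors, LRRN3, a neuronal leucine-rich repeat protein, NUCB2, the precursor of nesfatin, and IL27RA, a cytokine receptor subunit. NGFR was 38.0 ± 4.24 CPM in wild-type and 16.5 ± 2.70 CPM in knockout piglets (SD, n = 4 each), a log2 fold change of -1.20 ± 0.13 (SE, edgeR adjusted p = 0.0696). LRRN3 was 18.6 ± 3.76 and 7.04 ± 0.995 CPM (log2 fold change -1.40 ± 0.17, edgeR adjusted p = 0.0852). NUCB2, named by position, had a log2 fold change of -0.80 ± 0.11 (edgeR adjusted p = 0.132) and IL27RA of -0.69 ± 0.11 (edgeR adjusted p = 0.260). On the higher side stood TACC1, a centrosome-associated protein named by position (0.89 ± 0.14), the translation initiation factor subunit EIF3E (0.60 ± 0.10), the transporter chaperone EMB (0.62 ± 0.10), the amino acid receptor GPRC6A, named by position (1.70 ± 0.30), and the angiomotin-like junction protein AMOTL1 (0.50 ± 0.09), with edgeR adjusted p between 0.260 and 0.327. In all of these genes the 4 knockout values lay on 1 side of the 4 wild-type values, and DESeq2 called all 9. Without wild-type piglet 12 edgeR also called NGFR (adjusted p = 0.0404), LRRN3, NUCB2 and IL27RA (0.0448 each), and with no filter it called NGFR (0.0354) and LRRN3 (0.0425).

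CFTR was the only gene called by edgeR among 17175. None was called higher, with a smallest adjusted p of 0.255 on that side, while 1924 genes had an unadjusted p under 0.05, 921 higher and 1003 lower. The groups did not overlap in 998 genes (5.81%), against 2.86% by chance. The count depended on the tool. DESeq2 called 219 genes, 84 higher and 135 lower, with a median 1.49-fold change, and limma with sample quality weights called 11, 3 higher and 8 lower, all among the DESeq2 calls. Every one of the 219 genes had the same sign and an unadjusted p under 0.05 in edgeR, which used the same counts and so gives no independent support. Without wild-type piglet 12, edgeR called 19 genes and DESeq2 1069, and without wild-type piglet 9 DESeq2 called 52.

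Genes of the unfolded protein response, which fold proteins in the endoplasmic reticulum, were lower as a list in knockout piglets. Of 20 members tested, 15 had a negative log2 fold change, and the median was -0.30. Adjusted over the list alone, 9 members fell, namely the chaperones HYOU1, CALR, HSPA5 and HSP90B1, the disulfide isomerases PDIA4 and PDIA6, and CRELD2, MANF and SDF2L1, and 1 rose, the degradation adaptor SEL1L; over all genes none passed. HYOU1 was 227 ± 19.2 CPM in wild-type and 162 ± 4.77 CPM in knockout piglets (SD, n = 4 each), a log2 fold change of -0.49 ± 0.08. CALR, the calcium-binding lectin chaperone calreticulin, was 563 ± 122 and 317 ± 49.4 CPM (-0.83 ± 0.17). HSPA5, the chaperone BiP, was named after its values were seen and had a log2 fold change of -0.67 ± 0.16. The pro-apoptotic members DDIT3 and CHAC1, also named after their values were seen, had log2 fold changes of 0.19 ± 0.15 and 0.65 ± 0.27. DESeq2 called 7 of the list's genes lower. The camera adjusted p was 0.000135, but 0.675 as the adjusted p with an estimated correlation. The exact permutation p of the list score was 0.0571, and 0.4 adjusted over the lists.

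Cell cycle genes were lower as a list in knockout piglets. Of 30 members, 26 had a negative log2 fold change, with a median of -0.12. Adjusted over the list alone, 7 fell, the helicase subunits MCM2, MCM3, MCM4, MCM5 and MCM6, the loading factor CDC6 and the transcription factor E2F1; over all genes none passed. MCM3 was 27.0 ± 7.15 CPM in wild-type and 14.9 ± 0.981 CPM in knockout piglets (SD, n = 4 each), a log2 fold change of -0.86 ± 0.18. MCM2 had a log2 fold change of -0.72 ± 0.16. Other members, named after their values were seen, lay closer to 0, with MCM7, a subunit of the same helicase, at -0.04 ± 0.07, MKI67, a proliferation marker, at -0.08 ± 0.15 and TOP2A, a mitotic topoisomerase, at 0.03 ± 0.17. DESeq2 called MCM2, MCM3 and E2F1 lower. By camera the adjusted p was 0.00026, and the adjusted p was 0.675 with an estimated correlation, 0.164 without wild-type piglet 5 and 0.0596 without it and knockout piglet 18. The voom median was -0.12 with all libraries and -0.06 without wild-type piglet 5. In the list of globose basal cells and neuronal precursors, the dividing progenitors of the epithelium, 9 of 13 members were negative (median -0.08, camera adjusted p = 0.173). Adjusted over the list alone, PAX6, a transcription factor of these progenitors, fell from 62.1 ± 4.41 to 47.6 ± 4.29 CPM (SD, n = 4 each), and over all genes none passed.

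**Figure D2:**
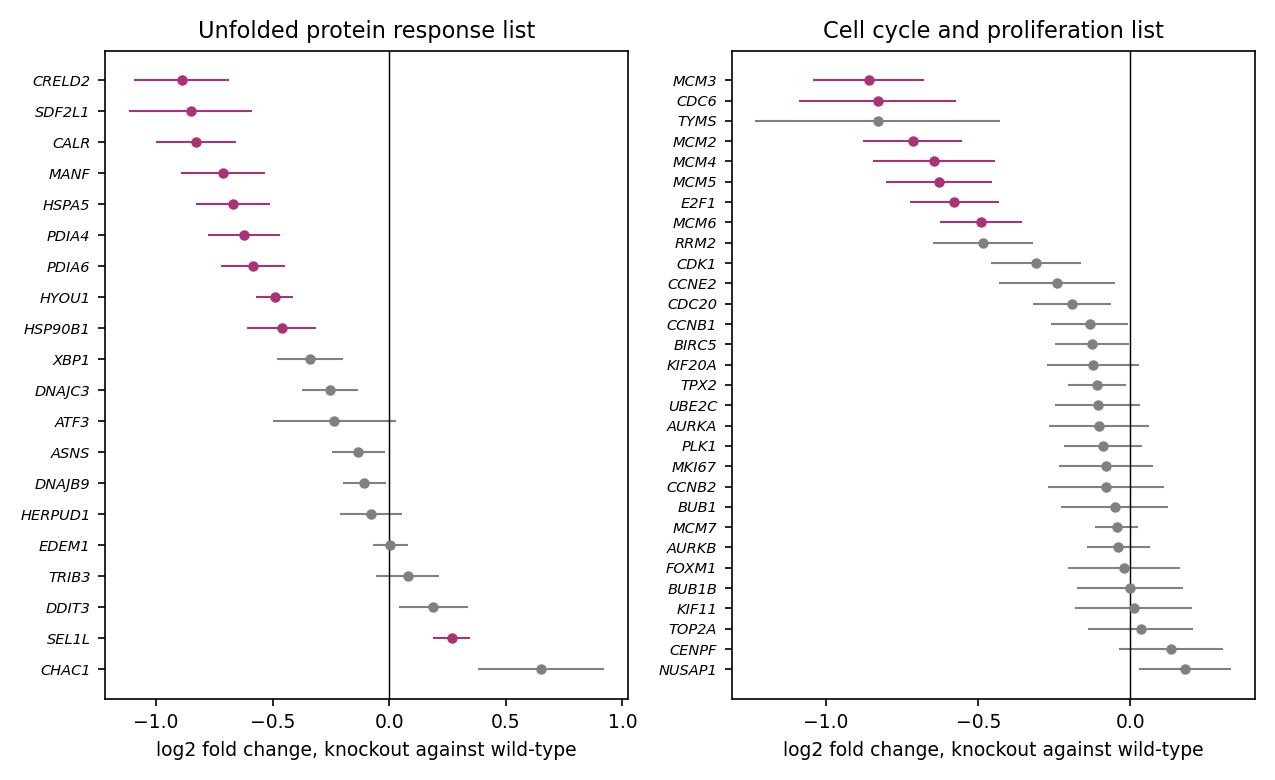
Log2 fold change of knockout against wild-type (horizontal axes) for the members of the unfolded protein response list and the cell cycle list, where points are edgeR estimates from 4 and 4 piglets, lines are 1 SE, and purple marks members past 0.05 adjusted over the list alone. Of the 20 unfolded protein response genes 15 lie below 0, and of the 30 cell cycle genes 26 do.

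Olfactory ensheathing and Schwann glia, which wrap the axons of the olfactory nerve, had lower markers as a list, negative in 11 of 14 members with a median of -0.41. NGFR was the member that fell adjusted over the list alone, and over all genes none passed. MBP, a myelin gene, had a log2 fold change of 0.29 ± 0.13 and did not pass. The camera adjusted p was 0.00534, and the adjusted p was 0.675 with an estimated correlation, 0.164 without wild-type piglet 5 (voom median -0.21, against -0.37 with all libraries) and 0.0596 without it and knockout piglet 18. The list of immediate early and heat shock genes, a sign of handling, was lower too, in 14 of 18 members with a median of -0.27 and none called adjusted over the list alone or over all genes. HSPH1, a heat shock protein, was 158 ± 40.3 CPM in wild-type and 96.1 ± 16.5 CPM in knockout piglets (SD, n = 4 each), and the immediate early gene FOS had a log2 fold change of -0.74 ± 0.29. Its camera adjusted p was 0.0143, and the adjusted p was 0.675 with an estimated correlation, 0.0913 without wild-type piglet 5, 0.103 without it and knockout piglet 18, 0.0526 without knockout piglet 6, 0.0619 with a filter at 1 CPM, 0.0824 with sample quality weights, 0.0616 with sex as a covariate, 0.0622 in the libraries with no EIF1AY or KDM5D read and 0.0920 in those without piglet 18. The voom median was -0.29 with all libraries, -0.39 without wild-type piglet 5, -0.35 without it and knockout piglet 18, -0.14 without knockout piglet 6, -0.11 with the filter, -0.36 with the weights and -0.13 in each of the last 3 fits.

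Mature olfactory sensory neurons had higher markers as a list, positive in 20 of 22 members with a median of 0.21. CNGA2, the olfactory cyclic nucleotide-gated channel, was 329 ± 79.1 CPM in wild-type and 458 ± 45.1 CPM in knockout piglets (SD, n = 4 each), a log2 fold change of 0.48 ± 0.17. RIC8B, which promotes olfactory G protein signalling, had 0.44 ± 0.15, CNGB1, named by position, had 0.67 ± 0.24, and the calcium-binding protein S100A5 had -0.51 ± 0.20. None passed adjusted over the list alone or over all genes. The camera adjusted p was 0.000544, and the adjusted p was 0.675 with an estimated correlation. Wild-type piglet 5 had the lowest list score of the 8 libraries (7.80, against 8.13 to 8.53 in the rest), and without it the adjusted p was 0.136 and the voom median 0.08, against 0.22 with all libraries and 0.18 (adjusted p = 0.0105) without it and knockout piglet 18. Immature neuron markers were positive in 15 of 20 members (median 0.09, camera adjusted p = 0.113), and the list was called higher without wild-type piglet 23 (0.0210), without knockout piglet 18 (0.0306) and with sex as a covariate (0.0228).

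Olfactory receptor genes were higher as a list in knockout piglets, in 47 of 58 tested genes with a median of 0.66 (camera adjusted p = 0.0111). The adjusted p was 0.675 with an estimated correlation, 0.300 without wild-type piglet 5, 0.346 without it and knockout piglet 18 and 0.0693 without knockout piglet 6. The voom median was 0.55 with all libraries and 0.21, 0.16 and 0.47 in these last 3 fits, and no receptor passed adjusted over the list alone or over all genes. Summed over 71 receptor genes, expression was 72.9 ± 23.2 CPM in wild-type and 112 ± 17.2 CPM in knockout piglets (SD, n = 4 each), a ratio of 1.54 with a two-sided exact permutation p of 0.0286, the smallest this design can give. For the list's mean log2 CPM, which weights each receptor equally, the exact permutation p was 0.2 (adjusted 0.431). Wild-type piglet 5 was lowest at 41.3 CPM. Reads of near-identical receptor genes cannot be assigned with certainty, so single receptor values are uncertain. Receptors were taken by symbol alone, and the tested ones had a median of 1.06 CPM. The rule fixed beforehand also allowed descriptions, which were not used. Any receptors among the 9701 identifiers with no symbol were left out, so these values do not cover the whole receptor repertoire.

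Tuft or chemosensory microvillous cells, rare sensory cells of the epithelium, had higher markers as a list, in 11 of 12 members with a median of 0.59. TRPM5, the cation channel of chemosensory cells, was 2.28 ± 0.623 CPM in wild-type and 4.49 ± 1.90 CPM in knockout piglets (SD, n = 4 each), and POU2F3, the transcription factor of tuft cells, was 0.784 ± 0.363 and 1.67 ± 0.545 CPM. None passed adjusted over the list alone or over all genes. The camera adjusted p was 0.00534, and the adjusted p was 0.675 with an estimated correlation and 0.0530 without knockout piglet 18 and wild-type piglet 5. The exact permutation p of the list score was 0.0571, and 0.4 adjusted over the lists.

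Epithelial ion and fluid transport genes were higher as a list, in 14 of 23 members with a median of 0.14. Adjusted over the list alone, 2 rose and over all genes none passed. SCNN1G, a subunit of the epithelial sodium channel, was 15.6 ± 1.14 CPM in wild-type and 21.3 ± 1.20 CPM in knockout piglets (SD, n = 4 each), a log2 fold change of 0.44 ± 0.09. ATP12A, the non-gastric proton pump, was 1.46 ± 0.333 and 3.14 ± 0.857 CPM (1.10 ± 0.27), and DESeq2 called both. SLC12A2, the sodium-potassium-chloride cotransporter that loads chloride into secreting cells, had a log2 fold change of 0.57 ± 0.18 and did not pass. By camera the adjusted p was 0.0495, and the adjusted p was 0.675 with an estimated correlation. The call ended without wild-type piglet 5 (adjusted p = 0.0818), 9 (0.0953) or 23 (0.129) or knockout piglet 6 (0.0714) or 21 (0.128), with DESeq2 size factors (0.0505), with sex as a covariate (0.0574) and in the libraries with no EIF1AY or KDM5D read (0.0600). The voom median, 0.13 with all libraries, was 0.02 without wild-type piglet 9 and 0.12 to 0.19 in the other fits that ended the call.

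Interferon response genes were higher as a list, in 15 of 19 members with a median of 0.34, and this rested on knockout piglet 21. The antiviral gene MX2 was 59.3 CPM in that piglet and 6.53 to 24.4 CPM in the others, and none of the list passed adjusted over the list alone or over all genes. The camera adjusted p was 0.0402, and the adjusted p was 0.745 with an estimated correlation, 0.664 without knockout piglet 21, 0.136 without wild-type piglet 5, 0.199 without wild-type piglet 12, 0.175 with sex as a covariate and 0.202 in the libraries with no EIF1AY or KDM5D read. The voom median was 0.29 with all libraries, 0.08 without knockout piglet 21 and 0.20 to 0.31 in the other fits. The inflammatory cytokine and NF-kB list was lower by camera (adjusted p = 0.386), although its edgeR median was 0.03 and its mean 0.21. CXCL8, a neutrophil-attracting chemokine, was 90.0 CPM in knockout piglet 21 and 2.14 to 10.3 CPM in the others. Without piglet 21 that list was called lower (adjusted p = 7.5e-05), with a voom median of -0.40 against -0.02 with all libraries.

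**Figure D3:**
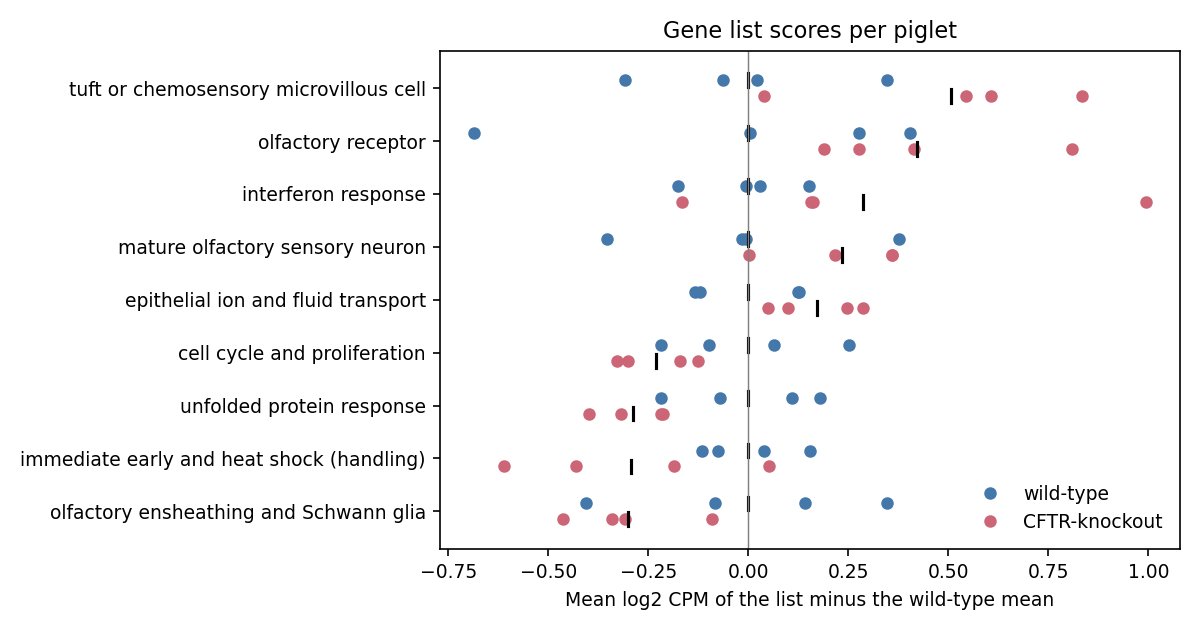
Mean log2 CPM of the 9 called lists in each piglet, minus the wild-type mean (horizontal axis, log2), with 4 wild-type piglets in blue, 4 CFTR-knockout piglets in red and group means as black bars. The groups overlapped in all 9 lists.

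Lists of the remaining epithelial cells were not called by camera. Sustentacular cells, the supporting cells of the epithelium, were negative in 10 of 14 members (median -0.28, camera adjusted p = 0.0858), with KRT18, a keratin, at -0.52 ± 0.21. The 4 knockout scores of this list (7.58 to 7.91) lay below the 4 wild-type scores (7.93 to 8.02), with an exact permutation p of 0.0286, the smallest possible, and 0.4 adjusted over the 28 lists. Secretory respiratory cells were negative in 10 of 12 (median -0.50, adjusted p = 0.0850), with AGR2, a mucin-folding isomerase, at -0.85 ± 0.30, and horizontal basal cells, the reserve stem cells, in 8 of 12 (median -0.08, adjusted p = 0.556). Bowman gland genes were positive in 8 of 13 (median 0.03, adjusted p = 0.628), ionocyte genes, which mark the airway cells richest in CFTR, in 7 of 11 (median 0.02, adjusted p = 0.417), and motile ciliated cell genes in 13 of 18 (median 0.05, adjusted p = 0.679). No member of these lists passed adjusted over the list alone or over all genes. The sustentacular list was called lower without wild-type piglet 9 (adjusted p = 0.0316) or knockout piglet 6 (0.0225) or 20 (0.0201). The secretory list was called lower without wild-type piglet 9 (0.0481) or 12 (0.00738), without knockout piglet 21 (0.0165) and with sex as a covariate (0.000791), which also gave a call for horizontal basal cells (0.0497).

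Knockout piglet 18 stood apart in genes of bone and connective tissue. COL1A1, the main collagen of bone, was 17394 CPM in this library and 313 to 2057 CPM in the other 7, and IBSP, bone sialoprotein, was 1839 and 1.15 to 117 CPM. COL1A1 took 1.56% of its reads, and mitochondrially encoded genes took 9.13% against 3.60% to 5.38% in the others. The cartilage and bone list, with an edgeR median log2 fold change of 0.95, had a voom median of 0.25 with all libraries (camera adjusted p = 0.442) and -0.40 without piglet 18 (adjusted p = 0.0129), and it was called higher without knockout piglet 6 (0.68, adjusted p = 0.0479). For fibroblasts and stroma the edgeR median was 0.27, and the voom medians were 0.13 (adjusted p = 0.919) and -0.35 without piglet 18 (adjusted p = 0.0121). The macrophage list was lower by camera (adjusted p = 0.949) although its edgeR median was 0.22 and its mean 0.23. Its voom median was 0.01, and without piglet 18 it was called lower at -0.26 (adjusted p = 0.0226).

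The remaining lists, of tissue outside the epithelium and of mitochondrially encoded genes, which mark no tissue, were not called by camera with all libraries. Endothelial genes were negative in 10 of 12 members (median -0.15, camera adjusted p = 0.173), mitochondrially encoded genes positive in 12 of 13 (median 0.30, adjusted p = 0.173), and erythroid genes positive in 5 of 5 (median 0.94, adjusted p = 0.0696). Skeletal muscle genes were positive in 5 of 5 (median 0.22, adjusted p = 0.314), lymphocyte genes in 7 of 9 (median 0.33, adjusted p = 0.449) and brain genes in 6 of 9 (median 0.14, adjusted p = 0.243). Endothelial genes were called lower without knockout piglet 18 (0.0226), without wild-type piglet 12 (0.0223) and with sex as a covariate (0.000383). Mitochondrially encoded genes were called higher without knockout piglet 6 (0.000729), and erythroid genes without wild-type piglet 23 (0.00570) or knockout piglet 6 (0.0155) or 20 (0.0465) and with a filter at 1 CPM (0.0399). The neutrophil list was lower by camera (adjusted p = 0.976) with a median of -0.000348 and a mean of 0.26. Y-linked EIF1AY and KDM5D had reads in wild-type piglets 9 and 12 and in none of the other 6, so libraries with these reads were 2 of 4 in the wild-type group and 0 of 4 in the knockout group. All genes on chromosome Y together took 894 and 868 CPM in piglets 9 and 12 and 195 to 261 CPM in the other 6.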

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

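The tests of piglet 18 against loss of CFTR, of handling, of sex, of wild-type piglet 5 and of neuroepithelium content were chosen after the results were seen, and the last pair was revised after first results, that of neuroepithelium content 3 times. In 88 tests of a measure within a group of 4 libraries, 8 held a library far from the other 3 (gap over range above 0.829). Chance gives about 1 in 20 for a single test, but the tests share the same libraries and the measures are related, so the rates are not comparable.

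In knockout piglet 18, COL1A1 took 1.56% of the reads against 0.0318% to 0.0674% in the other knockout piglets, and the cartilage and bone score was 7.05 against 3.60 to 4.09. Loss of CFTR as the source is argued against by the voom median of that list without this piglet, which was -0.403 (camera adjusted p = 0.0129). Bone in the dissected piece is a candidate source, since 10 osteoclast genes outside the fixed lists had a median log2 ratio to the other libraries of 2.73 (MAD 2.96). This was above all of 10000 random lists, but those held unrelated genes in a library already chosen for its bone and collagen genes, so the rank decides little. The erythroid (1.94), macrophage (1.35) and mitochondrially encoded (1.14) lists were high in this library too, unlike the mature neuron (-0.06) and motile ciliated (-0.29) lists. The rise was thus not particular to bone genes. ACP5, the osteoclast acid phosphatase, was 649 CPM against 2.73 to 72.7 in the other 7 libraries.

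The unfolded protein response list was called lower in knockout piglets by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.675). Sex as the whole source is argued against by the 6 libraries with no EIF1AY or KDM5D read. Their voom median was -0.454 (camera adjusted p = 4.0e-05 at the preset correlation). With the secretory respiratory score as a covariate, the knockout term of the list score was -0.276 ± 0.115 (SE), 96.0% of its size without. Fewer secretory cells stay open, since that score covers respiratory cells only and ranged from 3.80 to 5.38 within the wild-type group. Handling before freezing stays open, since 14 immediate early genes had an edgeR median of -0.214 (MAD 0.334) and a voom median of -0.26 (camera p = 0.0245), although the p was 0.221 with an estimated correlation and 0.229 by exact permutation. An effect of genotype stays open too.

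The mature neuron list was called higher in knockout piglets by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.675). The immature neuron list was not called (camera adjusted p = 0.113). Wild-type piglet 5 alone as the source was not decided, since the mature neuron list had an adjusted p of 0.136 without it but 0.0105 without it and knockout piglet 18. More neuroepithelium in the knockout pieces was not decided either, from 5 lists of other tissue (endothelium, stroma, cartilage and bone, macrophages and glia). Without knockout piglet 18 alone, 5 had a voom median below 0, and camera called each lower (adjusted p from 0.00231 to 0.0226). Without both piglets 5 had a voom median below 0, with endothelium at -0.04 and macrophages at -0.05, and camera called none of them (adjusted p from 0.0596 to 0.592). But 4 had one above 0 (0.11 to 0.40) without wild-type piglet 5 alone, and camera called none of these (0.205 to 0.631). That fit keeps knockout piglet 18, whose macrophage, stroma and cartilage and bone lists had median log2 ratios of 1.35, 1.55 and 2.44 to the other libraries. For these lists it therefore cannot count against more neuroepithelium. Sustentacular cells, part of the neuroepithelium, had lower scores in all 4 knockout piglets (7.58 to 7.91) than in the wild-type piglets (7.93 to 8.02). More neuroepithelium as a whole would not lower them. The list was not called, however (camera adjusted p = 0.0858, exact permutation p adjusted over the lists 0.4), so its scores do not decide the question. An effect of genotype stays open, as untested.

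Other single libraries lay far from the other 3 of their own group. Against the other 3 wild-type piglets, piglet 5 had a horizontal basal cell score of 5.87 (5.12 to 5.17), a brain and olfactory bulb score of 1.14 (0.888 to 0.899, with 1.04 to 1.35 in the knockout piglets) and 56.6 CPM of CFTR (34.0 to 36.6). Against the other 3 knockout piglets, LRRN3 was 5.56 CPM in piglet 6 (7.36 to 7.66), NUCB2 33.1 CPM in piglet 20 (39.7 to 40.5) and IL27RA 24.9 CPM in piglet 18 (21.7 to 22.2).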

How the results depend on the processing

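Alternatives for sex, stroma, adjusted deviances, gene-table symbols, pairs of left-out conditions and exact permutation of list scores were chosen after seeing the data. CFTR alone was called with DESeq2 size factors, upper quartile scaling, a filter at 1 CPM, a surrogate variable, sex as a covariate and a test against 1.5-fold. Called genes numbered 4 (4 lower) with no filter, 219 (84 higher, 135 lower) with DESeq2, 11 (3 higher, 8 lower) with limma and quality weights, 3 (3 lower) with adjusted deviances, 2 (2 lower) with stroma as a covariate, 0 (0 lower) in the libraries with no EIF1AY or KDM5D read, where CFTR was -2.77, 0 (0 lower) at an adjusted p of 0.01 and 4 (4 lower) at 0.1. Leaving out each library gave 0 to 19 called genes, 0 to 9 higher and 0 to 10 lower, and a CFTR log2 fold change of -2.67 to -2.36. Of the 5 lists called higher and 4 lower, 0 and 0 were called with an estimated correlation, with the directional test of fry and with exact permutation. For exact permutation this says little, since no p can fall below 0.0286 before adjustment over the 28 lists. The mixed test of fry, which takes changes in either direction together, called 4 lists. These were glia (adjusted p = 0.00383), the unfolded protein response (0.0104), ion transport (0.0104) and brain (0.0320), the last not called by camera. The mixed test does not show that a list as a whole moved 1 way. The unadjusted exact permutation p was 0.0571 for the unfolded protein response and tuft lists, 0.114 for cell cycle, 0.143 for handling and 0.171 for glia and for ion transport. It was 0.2 for receptors, 0.257 for mature neurons and 0.314 for interferon. Leaving out each library gave 1 to 6 lists higher and 1 to 8 lower. Without knockout piglet 18 and wild-type piglet 9, 9 lists were lower, and 8 were in the libraries with no EIF1AY or KDM5D read and not piglet 18. Without knockout piglet 18 and wild-type piglet 5, 3 lists were higher and 1 lower. Voom medians reversed for fibroblasts (-0.35 without piglet 18, -0.39 without 18 and 9, -0.65 with no EIF1AY or KDM5D read and not 18), for cartilage and bone (-0.40, -0.32 and -0.57) and for mitochondrially encoded genes (-0.13 without 18 and 9). Another 10 lists, none called with all libraries, had a voom median of the other sign under at least 1 alternative, among them macrophages (0.01 to -0.66), erythroid cells (0.85 to -0.10), endothelium (-0.13 to 0.11), horizontal basal cells (-0.07 to 0.21), secretory cells (-0.24 to 0.03) and Bowman gland (0.06 to -0.43). Over all left-out libraries the voom medians of fibroblasts and of cartilage and bone ranged from -0.35 to 0.40 and from -0.40 to 0.68. Fewer samples or a stricter threshold are part of some of these alternatives, and otherwise the cause was not tested. No paired analysis was possible because the groups share no piglet numbers. The planned covariate of Y-linked genes did not meet its condition, since reads of EIF1AY and KDM5D occurred in the wild-type group only. Sex as a covariate, taken from the same reads, was added after the data were seen, and its effect rests on the wild-type group alone. With 4 libraries a group, changes under 2-fold were often missed in simulated data.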

Other observations

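The tests of chaperones and of genes near CFTR were chosen after results were seen, and for the latter the bound that would have argued against it was widened to its interval after its value was known. Genes named here were chosen after their values were seen. Cytosolic chaperones, which fold proteins outside the endoplasmic reticulum, were lower in knockout piglets. HSPA8, the constitutive heat shock cognate, was 1825 ± 430 CPM in wild-type and 926 ± 151 CPM in knockout piglets (SD, n = 4 each), a log2 fold change of -0.98 ± 0.18 (edgeR adjusted p = 0.327). In 24 other chaperone genes, listed after the top genes had been seen, 23 were lower with a voom median of -0.28 (camera p = 3.3e-12), but the p was 0.0900 with an estimated correlation and 0.0571 by exact permutation. Members such as CHORDC1 were themselves called by DESeq2, so the list is not independent of the data. A shared fall of cytosolic chaperones is thus a hypothesis.

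PAEP, a lipocalin, was 1.36 ± 0.768 CPM in wild-type and 0.0173 ± 0.0115 CPM in knockout piglets (SD, n = 4 each), with a log2 fold change of -6.02 ± 0.73 (edgeR adjusted p = 0.0852). The 71 RPL and RPS genes of the ribosome, tested as a set because EIF3E had a small p, had a voom median of 0.04 and were not called (camera p = 0.242, exact permutation p = 0.857).

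LRRN3 lies on the chromosome of CFTR, at 34425836 to 34465665 and thus within 10 Mb of it. A founder chromosome around the disrupted gene may carry other differences. Of 84 genes within 10 Mb other than CFTR and LRRN3, 8 had an unadjusted p under 0.05 (9.52%, against 11.2% of 17089 elsewhere, Fisher's exact p = 0.731, odds ratio 0.835 with a 95% interval of 0.347 to 1.73). The ratio of these shares was 0.850, with 13 of 35 splits of the libraries as large and 2.67 as the highest other. In the rest of chromosome 18 the share was 17.3% of 248 genes. Of the genes within 10 Mb, ZNF277 (log2 fold change 0.54, DESeq2 adjusted p = 0.00210) and GPR37 (-0.42, 0.0129) were among the 219 DESeq2 calls. This leaves the explanation open.

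Chance cannot be excluded for the counts of calls. Of 35 splits of the 8 libraries, 6 called as many genes by edgeR (real 1, highest other 46), 3 by DESeq2 (real 219, highest other 1449) and 24 as many lists (real 9, highest other 15). For genes the highest split by both tools set wild-type piglets 5, 9 and 23 with knockout piglet 18 against the rest, which points to a structure of the samples that was not tested. For lists the split of wild-type piglets 5 and 9 with knockout piglets 18 and 21 gave 15 as well.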
